A study of Mus musculus with 14 samples.

How the data were processed

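Gene expression was measured with 1-colour arrays (Agilent design 028005) in mPFC tissue of 14 mice, 1 mouse per array: 5 naive, 6 susceptible and 3 resilient. Group and mouse number were taken from the labels. Per the labels' protocols, mice were perfused at 4 h after the last session, tissue was punched (1.5 mm), and 35 ng of RNA per array was labelled with Cy3 using a low-input kit. The labels mention independent experiments with different mice but do not say which mouse belongs to which, so experiment was not analysed here.

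Per the file headers, the deposited scanner tables come from Agilent Feature Extraction 11.0.1.1 and hold spot intensities on a linear scale, and the processed signal used here is the scanner software's own background-subtracted intensity, not normalised between arrays. The value table deposited by the authors holds log2 values of the same arrays. Set against the scanner signals, its columns correlated at r = 1 and differed from log2 of the processed signal only by 1 constant per array, which places the 75th percentile over all of its probes at 0. Genes were not centred, direction and scale are those of log2 signal, and the column medians lay between -3.09 and -2.74.

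Each array had 62976 spots, of which 3671 were controls and were left out. Spots of 1 probe were averaged after leaving out spots the scanner software marked as outliers (104 to 184 per array), which gave 55681 probes. The signal was taken as log2 and each array's 75th percentile was subtracted. A probe entered the tests when it was well above background on all arrays of at least 1 group (29813 probes). Gene names came from transcript accessions matched without versions to a RefSeq gene table of assembly GRCm38.p6, used for names alone since the headers name an older build. Of the probes, 27509 received a gene name (20887 genes) and 28172 did not, and the latter stayed out of the gene counts. Names rest on the accession alone, and probe specificity was not analysed here. For a gene with several probes, the one with the highest mean signal was used. This left 14453 genes; 7 more were left out because an array had an outlier spot.

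Groups were compared with limma 3.58.1 in R 4.3.3, in 1 fit of all 14 arrays with 3 groups and no covariate (lmFit, eBayes), and p-values were adjusted by Benjamini-Hochberg over the genes tested, with calls at adjusted p under 0.05. Differences are log2 values with the fit's standard error (SE). Where no array of a group was well above background, the fold is a bound: the mean of the brighter group against the mean, over the dimmer group's arrays, of the higher of the gene's own signal and the lowest signal well above background. The 29 gene lists, 14 functional and 15 of cell type markers, were tested with camera (preset correlation 0.01) on the lists' tested genes, with p adjusted over all 87 lists and comparisons, and again with an estimated correlation, with which 0 of the 28 calls held. The pipeline was checked on simulated arrays of 14453 genes with 200 changed: for susceptible against naive 28.4%, 85.1% and 98.5% of changes of 0.5, 1 and 2 were recovered, and for resilient against naive 14.3%, 72.5% and 95.5%. Noise was drawn independently for each gene there, unlike in real arrays, so these shares may not hold for the real arrays.

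The groups, tests, 29 gene lists, first set of alternatives and the rule for named genes were chosen before the data were examined. The rule took, per comparison, the 10 largest rises and 10 largest falls among genes past the threshold, then up to 4 members of each functional list by smallest p. It took values of 2 members where a list had none past the threshold, and of the 5 smallest p in a direction with fewer than 5 calls; Tlr2, Tlr4, Il1a and Tnf were fixed by name. Some genes that the rule takes are not reported here. Further list members that passed are named in the counts of their lists. Map3k6, Hif3a, Klf9, Tsc22d3, Cdkn1a, Slco1a4, S100b and Adora2a fall outside the rule and were added after their values were seen.

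Alternatives were quantile normalisation, normexp background correction (offset 50), other filters and thresholds, the mean of a gene's probes, the authors' value table, slide or scan day as a block, array weights, eBayes with trend and robust settings, a replicate block, only the groups compared, and leaving out each mouse. For normexp the median spot and background intensities were used, as the mean spot intensity was not used here. Fits with array brightness or meningeal markers as covariates, and with the arrays of 1 scan day, were added after the data were seen, as were lists of neutrophil, inflammation response and ribosomal protein genes. Array weights did not reach their convergence tolerance. Comparisons against the same naive mice were set against 200 simulations of unchanged groups.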

Results

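Gene expression was measured in the medial prefrontal cortex (mPFC), a frontal cortical region involved in emotional and social behaviour, of 14 wild-type C57BL/6 mice. In repeated social defeat stress a mouse is exposed again and again to an aggressive mouse, and defeated mice are afterwards classed by behaviour. The labels class 6 of the defeated mice as susceptible and 3 as resilient, and 5 naive mice were moved between cages instead. Tissue was punched (1.5 mm) from perfused brains at 4 h after the last session, and 35 ng of RNA from each mouse was hybridised to its own array with 1 dye (Cy3). The mice are separate animals, and the spread within a group holds differences between mice and between the slides of their arrays. Of the genes on the array, 14453 were tested. Between 48.0% and 65.4% of the spots on an array were well above background, no spot was saturated, and the number of arrays limits the precision.

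The arrays lay on 3 slides scanned on 2 days. Slides 1 and 2 held mice of all 3 groups, and slide 3, scanned on the other day, held 2 naive and 2 susceptible mice. All naive arrays lay in row 1 of their slide and all arrays of defeated mice in row 2, so slide row and defeat cannot be told apart. The 75th percentile of the log2 signal, a measure of array brightness, was 7.82 ± 0.71 (SD, n = 5) in naive, 8.22 ± 0.61 (n = 6) in susceptible and 8.03 ± 0.12 (n = 3) in resilient mice. The mean of the naive arrays was below that of the susceptible arrays on each slide, at 7.31 against 7.99 on slide 1, 7.30 against 7.73 on slide 2 and 8.59 against 8.93 on slide 3. The difference on slide 3 came from susceptible 5 (9.24), as susceptible 6 (8.63) lay between naive 4 (8.54) and naive 5 (8.64).

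**Figure D1:**
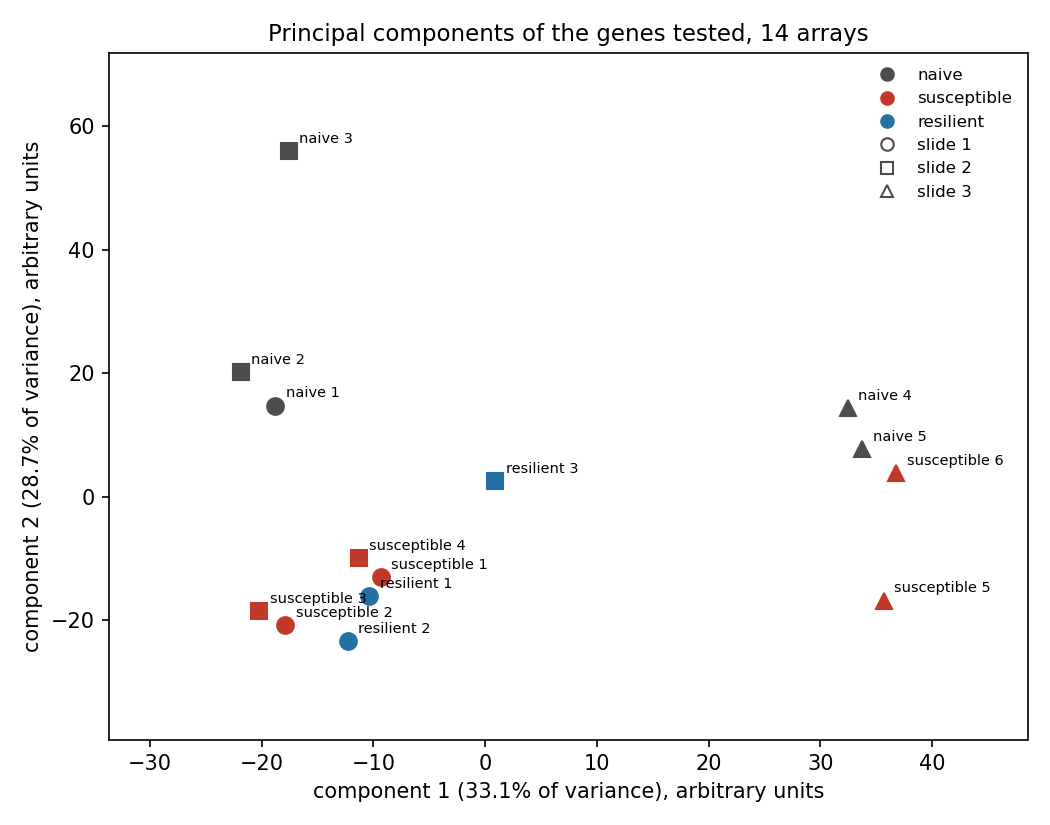
Principal components of the 14 arrays over the genes tested: the horizontal axis is component 1 (33.1% of the variance), the vertical axis component 2 (28.7%), both in arbitrary units, with colour for group and shape for slide. The 4 arrays of slide 3 lay at 32.5 or above on component 1, and naive mice lay higher on component 2 than the susceptible mice, from 7.64 to 56.0 in naive mice.

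Susceptible mice were compared with naive mice to ask which transcripts differed after defeat in mice classed as susceptible. The leading rises included S100a8, S100a9 and Lcn2. S100a8, a calprotectin subunit abundant in neutrophils, was well above background in 5 of 6 susceptible mice and in 0 of 5 naive mice, so its fold is given as a bound, at least 4.97-fold higher (limma adjusted p = 0.0149). Its partner S100a9 was 3.53 ± 0.64 higher on the log2 scale (SE, n = 6 and 5; adjusted p = 0.0233; above background in 4 of 5 naive mice). Lcn2, which encodes the iron siderophore-binding protein lipocalin 2, was 3.36 ± 0.42 higher (adjusted p = 0.0149), a 10.3-fold difference, and lay above every naive value in 6 of 6 susceptible mice.

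Other leading rises were Scgb3a1, a secreted secretoglobin (2.87 ± 0.52; above background in 2 of 5 naive mice), and Lrg1, a secreted acute phase glycoprotein (2.32 ± 0.39). Tmem52, which encodes a membrane protein, was above background in 6 susceptible and 0 naive mice and at least 2.72-fold higher. Lao1, an L-amino acid oxidase, rose by 1.70 ± 0.28, and Fmo2, a flavin-containing monooxygenase, by 1.48 ± 0.31; both were above background in only some naive mice, 2 and 3 of 5. Plin4, a lipid droplet coat protein, rose by 1.42 ± 0.26, and Fkbp5, a co-chaperone of the glucocorticoid receptor, by 1.37 ± 0.26. The largest falls were smaller. Fabp7, the brain fatty acid-binding protein of astrocytes, fell by 1.21 ± 0.19 on the log2 scale, and Icam2, an endothelial adhesion molecule, fell by 1.30 ± 0.25. Aif1l, an actin-binding protein, fell by 1.32 ± 0.21, Serpinb1a, an inhibitor of neutrophil proteases, fell by 1.19 ± 0.24, and Itm2a, a membrane protein, fell by 1.24 ± 0.28. Mboat1, a lysophospholipid acyltransferase, fell by 1.24 ± 0.26 and was above background in 4 of 6 susceptible mice. Spem2 (-1.38 ± 0.29), Olfr1415 (-1.33 ± 0.30), Prr5l (-1.24 ± 0.28) and Myom3 (-1.23 ± 0.26) completed the 10 largest falls; Spem2 and Olfr1415 are named by probe accession alone, and the specificity of their probes was not tested. Adjusted p in limma lay between 0.0149 and 0.0392 for these 20 genes.

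**Figure D2:**
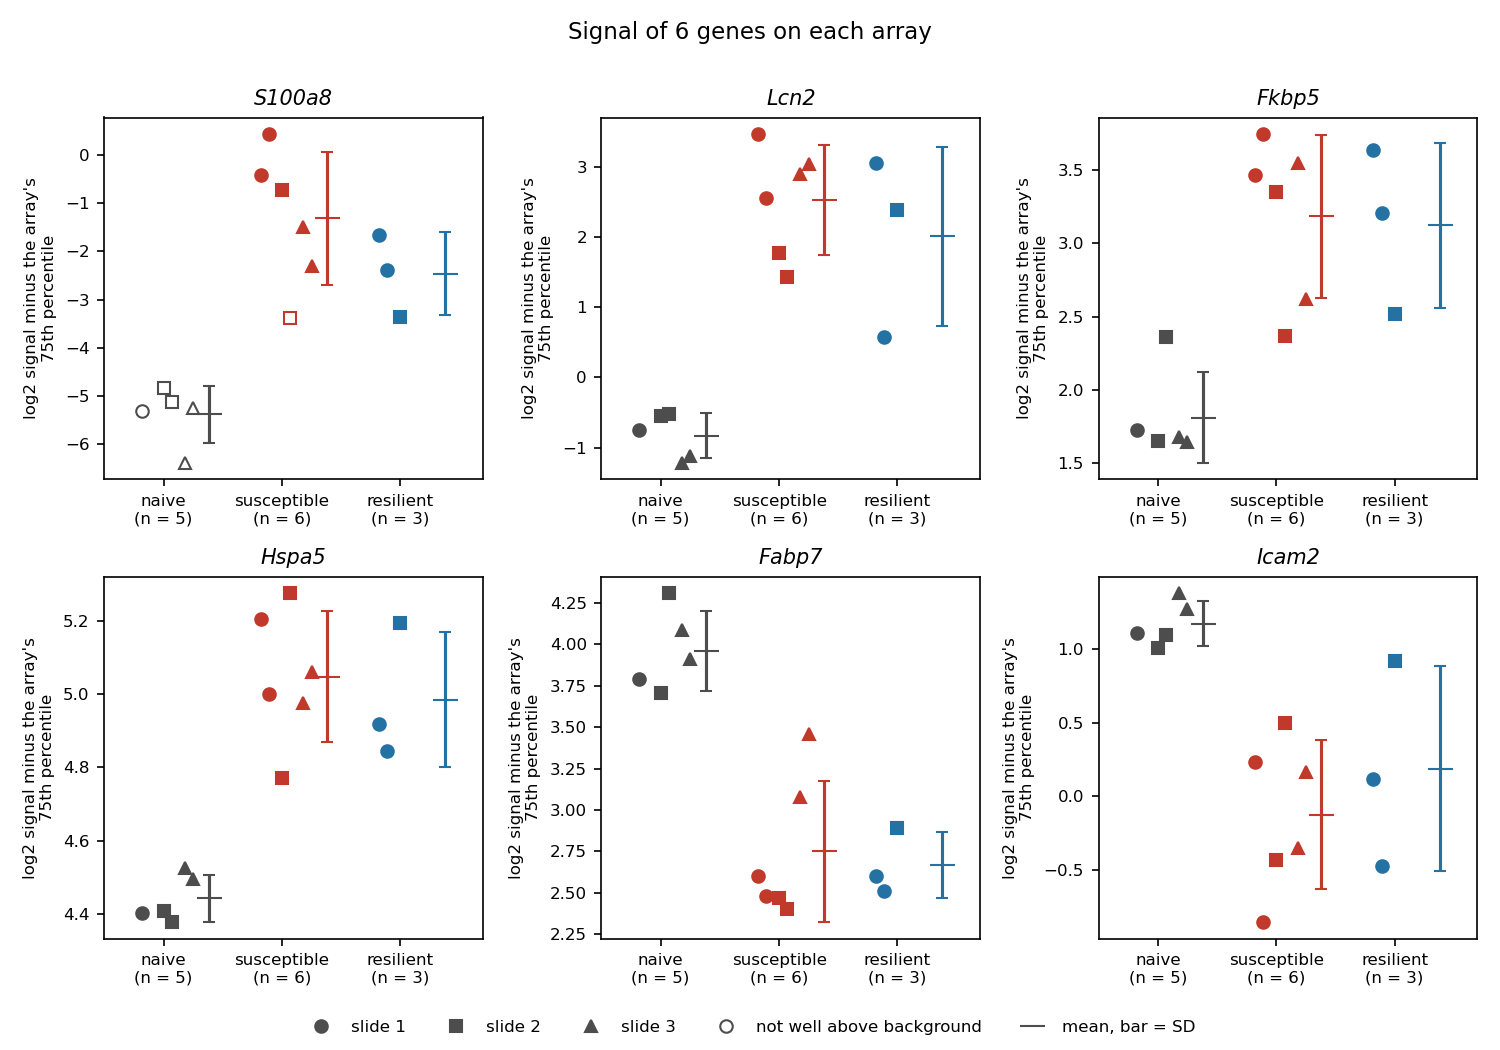
Normalised log2 signal of 6 genes on each array (vertical axes, log2 signal minus the array's 75th percentile) in naive, susceptible and resilient mice, with each group's mean and SD, shapes for the slides and open symbols for spots not well above background. S100a8, Lcn2, Fkbp5 and Hspa5 lay above, and Fabp7 and Icam2 below, every naive value in 6 of 6 susceptible mice.

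In all, 376 of 14453 genes passed an adjusted p of 0.05 in limma, 237 higher and 139 lower in susceptible mice, and 44 of them differed at least 2-fold. The same test with slide as a block gave 2213 genes, 1276 higher and 937 lower, and these held all 376. Within each of the 3 slides, which hold 1 or 2 mice per group and are part of the pooled data that chose the genes, all 376 differed in the pooled direction, by a median of 0.57, 0.80 and 0.42 on the log2 scale, while each slide alone passed 20, 2022 and 0 genes. The count depended on single mice: it was 27 without susceptible 1, 43 without susceptible 2, 138 without susceptible 3, 67 without susceptible 4, 62 without susceptible 5 and 869 without susceptible 6. It was 235, 59, 57, 148 and 571 without naive 1, 2, 3, 4 and 5, and 217 and 240 without resilient 1 and 2. Of the 29 genes named for this comparison that passed, 23 lost their call when some array was left out (highest adjusted p 0.0917), none changed sign, and 28 kept it in each such fit with slide as a block.

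Genes known to be induced by glucocorticoids, the adrenal stress hormones, had a median of 0.63 (camera adjusted p = 1.70e-07; adjusted p = 0.569 with an estimated correlation of 0.463). Of 20 genes in this list, 9 rose and 0 fell over all genes tested, and 12 rose adjusted over the list alone. Besides Lcn2, Plin4 and Fkbp5 the members that rose were Zbtb16, a transcriptional repressor (0.94 ± 0.18), Tsc22d3, the leucine zipper protein GILZ (1.09 ± 0.23), Cdkn1a, a cell cycle inhibitor (1.13 ± 0.28), Map3k6, Hif3a and Klf9. For the list 6 of 6 susceptible mice lay above the naive mean. In the fit with slide as a block its median was 0.60 and its camera adjusted p 3.69e-05, or 0.804 with an estimated correlation. Within slides 1, 2 and 3 its median was 0.89, 0.29 and 0.63.

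Endoplasmic reticulum stress genes, which encode chaperones and regulators of protein folding, had a median of 0.33 (camera adjusted p = 2.51e-05; adjusted p = 0.527 with an estimated correlation). Of 15 genes 2 rose over all genes tested, the chaperone Hspa5 (0.61 ± 0.10) and Creld2 (0.58 ± 0.13), 10 rose adjusted over the list alone, with 6 of 6 mice above the naive mean. Its median with slide as a block was 0.32 (camera adjusted p = 1.34e-04, or 0.691 with an estimated correlation). Within slides 1, 2 and 3 the median was 0.38, 0.32 and 0.31.

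Immediate early genes, the rapid markers of neuronal activity, shifted upward by a median of 0.15 (camera adjusted p = 0.0182; adjusted p = 0.569 with an estimated correlation). Of 22 genes 1 rose, over all genes tested and adjusted over the list alone, the synaptic regulator Arc (0.89 ± 0.20). The block median was 0.17 (camera adjusted p = 0.0226, or 0.691 with an estimated correlation). The medians within slides were 0.29, 0.32 and 0.14. Cytosolic heat shock genes shifted by 0.20 (camera adjusted p = 0.0295; adjusted p = 0.604 with an estimated correlation), with 1 of 14 past the threshold, the HSP90 co-chaperone Chordc1 (0.67 ± 0.12), and 4 adjusted over the list alone. Their block median was 0.21 (camera adjusted p = 0.0392, or 0.804 with an estimated correlation). Their medians within slides were 0.27, 0.16 and 0.14. Circadian clock genes did not pass as a set by camera (median 0.02; camera adjusted p = 0.122; adjusted p = 0.569 with an estimated correlation). They passed upward by fry, another test of sets (fry adjusted p = 0.032). Of 15 genes 3 rose, over all genes and adjusted over the list alone: Per3 (0.74 ± 0.16), Bhlhe40 (0.64 ± 0.13) and Per2 (0.45 ± 0.10). The clock median was 0.01 with slide as a block and 4 genes rose there, and within slides it was 0.09, 0.36 and 0.08.

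Among monoamine receptor and enzyme genes, 1 of 14 rose, the serotonin 2A receptor Htr2a (0.91 ± 0.15; adjusted p = 0.0175), higher in 6 of 6 susceptible mice than in any naive mouse. The set did not pass, and its median of -0.05, its mean of 0.05 and its test, downward at a camera adjusted p of 0.894, differ in sign. Toll-like receptor and inflammatory cytokine genes did not pass as a set (median 0.15; camera adjusted p = 0.631): 2 of 17 rose, S100a8 and S100a9, and 5 rose and 2 fell adjusted over the list alone, as did 5 and 2 over all genes with slide as a block. The probes for Tnf, Il1a, Il1b and Il6 were well above background on 0 of 14 arrays. Tlr2 was above background on 9 arrays (3 of 5 naive, 4 of 6 susceptible and 2 of 3 resilient) and was not tested, and Tlr4 was -0.92 ± 0.29 against naive (adjusted p = 0.0882), above background in 3 of 6 susceptible and 5 of 5 naive mice. Its fall passed with slide as a block (adjusted p = 0.0350), but not in every such fit with 1 mouse left out (highest 0.106).

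The remaining functional lists did not pass as sets and had 0 genes past the threshold without a block. In the fit with slide as a block they had 1 rise and 4 falls among antioxidant genes, 2 and 2 among presynaptic and among neuropeptide genes, and 1 and 1 among interferon and among glutamate genes. There was 1 rise among cholesterol genes and 1 fall among oxidative phosphorylation genes. Median shifts and camera adjusted p were -0.36 and 0.198 for interferon response genes, 0.04 and 0.695 for glutamate receptor and postsynaptic genes, 0.17 and 0.271 for presynaptic vesicle genes, and 0.08 and 0.760 for cholesterol synthesis genes. They were 0.21 and 0.475 for neuropeptide and stress hormone genes, -0.02 and 0.526 for antioxidant response genes, and 0.01 and 0.556 for oxidative phosphorylation genes, whose mean was -0.06. The members with the smallest p included Nr3c1, the glucocorticoid receptor (-0.40 ± 0.11; adjusted p = 0.0595), and Sst, somatostatin (0.55 ± 0.16; 0.0756). Gria3 (0.40 ± 0.11), Grin1 (0.37 ± 0.12), Syp (0.42 ± 0.13), Pclo (-0.39 ± 0.11), Stat2 (0.29 ± 0.09) and Psmb8 (-0.50 ± 0.17) had adjusted p between 0.0616 and 0.0993. Insig1 (0.44 ± 0.12), Hmgcs1 (-0.34 ± 0.12), Prdx1 (-0.38 ± 0.11), Txnrd1 (0.24 ± 0.08), Ndufb8 (-0.32 ± 0.12) and Cox6c (-0.50 ± 0.16) had adjusted p between 0.0673 and 0.135. The block changed these calls for all but Grin1, Hmgcs1 and Ndufb8: adjusted p with slide as a block was 0.0256 for Nr3c1, 0.0484 for Sst, 0.0328 for Gria3, 0.0490 for Syp, 0.0343 for Pclo and 0.0359 for Stat2. It was 0.0480 for Psmb8, 0.0368 for Insig1, 0.0354 for Prdx1, 0.0319 for Txnrd1 and 0.0269 for Cox6c. Each of these 11 lost that call when some mouse was left out (highest adjusted p from 0.0691 to 0.160).

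Cell type markers moved with the groups too. Meningeal fibroblast markers were lower in susceptible mice by a median of -1.06 (0 of 8 genes past the threshold; camera adjusted p = 0.00895; adjusted p = 0.599 with an estimated correlation), at -1.31, -1.22 and -0.61 within slides. Pericyte or smooth muscle markers had a median of -0.84 (camera adjusted p = 0.0317; adjusted p = 0.599 with an estimated correlation). Endothelial markers had a median of -0.45 (camera adjusted p = 0.0171; adjusted p = 0.569 with an estimated correlation), with 1 of 7 genes past the threshold, the blood-brain barrier transporter Slco1a4, which fell by 0.73 ± 0.16. Astrocyte markers had a median of -0.27 (camera adjusted p = 0.0179; adjusted p = 0.569 with an estimated correlation), with 1 of 9 past the threshold, S100b, which fell by 0.64 ± 0.16. Erythroid genes, mostly globins, had a median of 1.59 (camera adjusted p = 0.0134; adjusted p = 0.599 with an estimated correlation), with 0 of 5 genes past the threshold and 5 adjusted over the list alone. Blood leukocyte markers had a median of 0.36 (camera adjusted p = 0.0134; adjusted p = 0.527 with an estimated correlation), with 2 of 5 rising, S100a8 and S100a9. Neuron markers shifted by 0.22 (camera adjusted p = 0.0367; adjusted p = 0.599 with an estimated correlation) and inhibitory neuron markers by 0.25 (camera adjusted p = 0.0305; adjusted p = 0.569 with an estimated correlation), with 0 genes past the threshold; within slide 3 the neuron median was -0.01.

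With slide as a block the camera adjusted p stayed under 0.05 for meningeal (0.0313), erythroid (0.0313), blood leukocyte (0.0313) and astrocyte markers (0.0403). None of these block calls held with an estimated correlation (camera adjusted p from 0.691 to 0.804). The block camera adjusted p was 0.0544 for endothelial, 0.103 for pericyte, 0.121 for neuron and 0.121 for inhibitory neuron markers. In the fit with slide as a block 3 inhibitory neuron, 3 blood leukocyte, 1 oligodendrocyte precursor, 1 striatal and 1 erythroid marker rose. The falls were 2 astrocyte, 2 endothelial, 2 microglia, 1 striatal, 1 cortical excitatory, 1 oligodendrocyte and 1 choroid plexus marker. The other marker lists did not pass. Their medians and camera adjusted p were -0.04 and 0.648 for cortical excitatory neurons, 0.22 and 0.727 for striatal neurons (1 of 8 genes, Adora2a, fell by 0.45 ± 0.08), and -0.35 and 0.0508 for oligodendrocytes. They were 0.00 and 0.805 for oligodendrocyte precursors, 0.02 and 0.700 for microglia (mean -0.05), -0.92 and 0.107 for perivascular macrophages, and 0.02 and 0.727 for choroid plexus (mean -0.34).

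**Figure D3:**
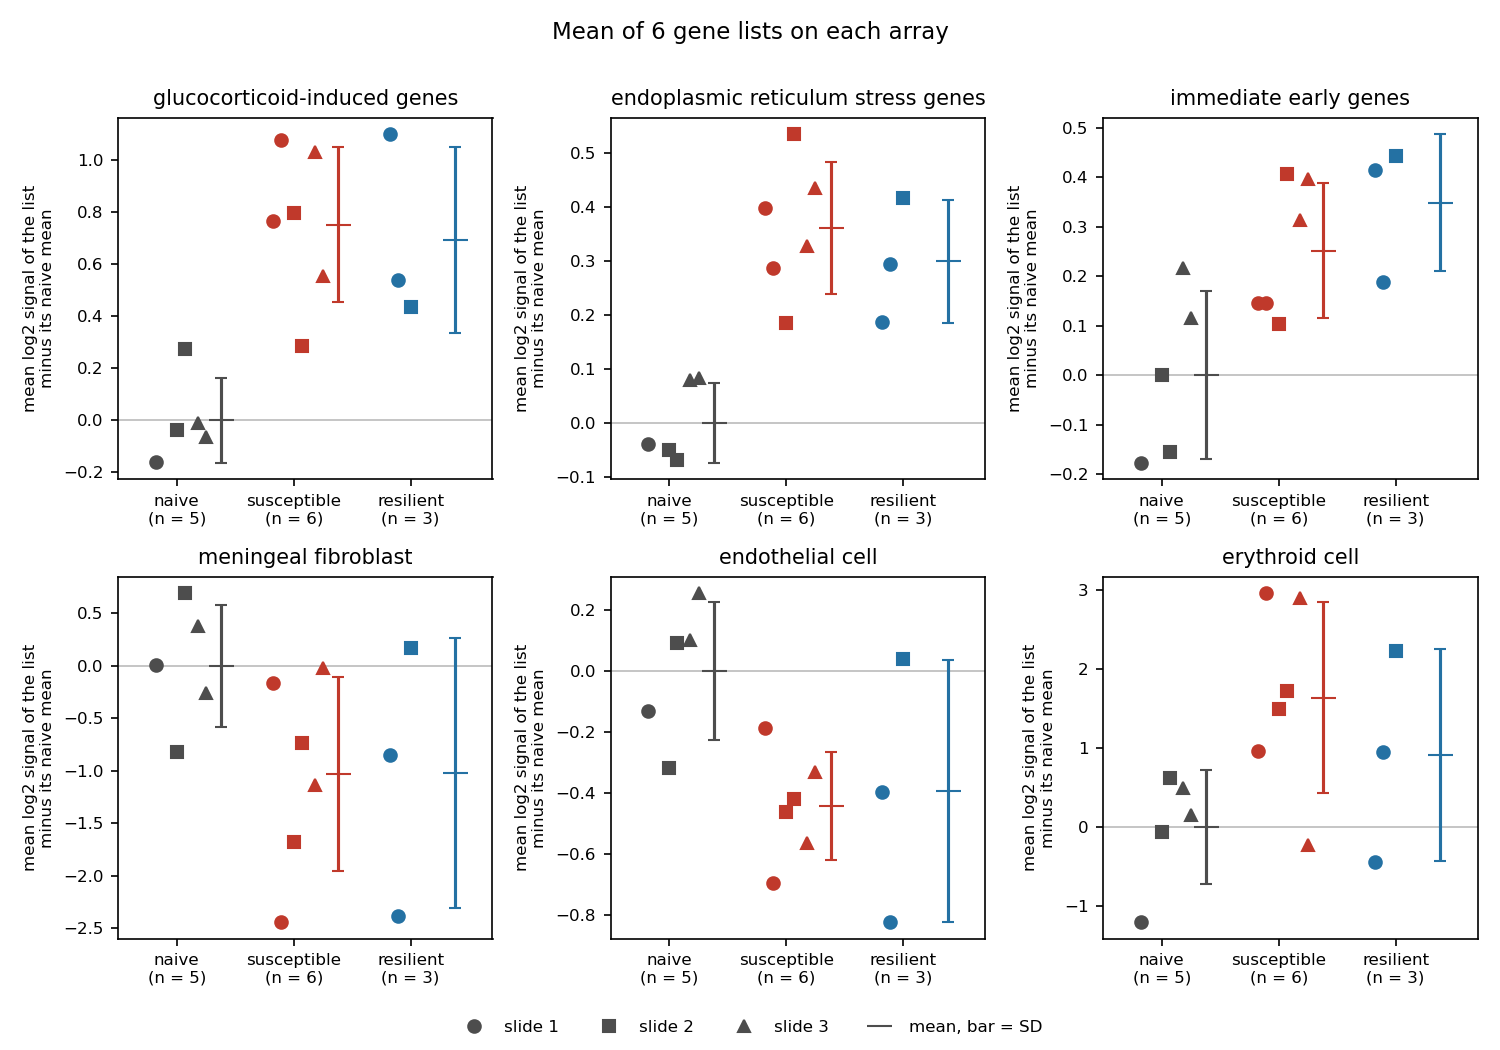
Mean log2 signal of 6 gene lists on each array minus the naive mean of the list (vertical axes), by group, with mean and SD and shapes for the slides. In 6 of 6 susceptible and 3 of 3 resilient mice the glucocorticoid-induced and endoplasmic reticulum stress lists lay above the naive mean, while the meningeal list lay below it in 6 of 6 susceptible and 2 of 3 resilient mice.

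Resilient mice were compared with naive mice to ask which transcripts differed in defeated mice classed as resilient. Here 22 of 14453 genes passed in limma, 13 higher and 9 lower. None passed with normexp background correction, with no filter on dim probes or with a filter on 3 arrays (2256, 2941 and 2995 genes at an unadjusted p under 0.05). Lcn2 was again among the largest rises (2.84 ± 0.51; SE, n = 3 and 5; adjusted p = 0.0436). Thsd4, a secreted thrombospondin-type protein, rose by 1.84 ± 0.27 (above background in 2 of 5 naive mice). Adamts3, a procollagen-processing protease, was above background in 3 of 3 resilient and 0 of 5 naive mice and at least 1.53-fold higher. Pkp2, a desmosomal plaque protein, rose by 1.39 ± 0.24, and Slc24a4, a sodium-calcium exchanger, by 1.16 ± 0.19. Ankrd52 (0.96 ± 0.16), Rsrp1 (0.91 ± 0.15), Map2k6, a kinase upstream of p38 (0.89 ± 0.14), Spata2l (0.81 ± 0.15) and Usp53 (0.81 ± 0.13) completed the largest rises. Aif1l and Fabp7 led the falls, by -1.43 ± 0.25 and -1.29 ± 0.23. Dlx3, named by probe accession alone (-1.26 ± 0.22), S100a16 (-0.97 ± 0.14), the endocytic adaptor Ston2 (-0.97 ± 0.15), Lgi4 (-0.89 ± 0.13), Rom1 (-0.89 ± 0.15) and the RNA Snhg6 (-0.76 ± 0.13) also fell. All 18 of these lay beyond every naive value in 3 of 3 resilient mice.

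In the same comparison the glucocorticoid-induced list had a median of 0.63 (camera adjusted p = 2.50e-06; 1 of 20 past the threshold, 11 adjusted over the list alone; adjusted p = 0.569 with an estimated correlation). Endoplasmic reticulum stress genes shifted by 0.27 (camera adjusted p = 0.00274; 0 of 15, and 3 adjusted over the list alone; adjusted p = 0.569 with an estimated correlation), with Hspa5 at 0.54 ± 0.12 (adjusted p = 0.0734). Immediate early genes shifted by 0.33 (camera adjusted p = 0.00261; 0 of 22, and 7 adjusted over the list alone; adjusted p = 0.527 with an estimated correlation) and circadian genes by 0.28 (camera adjusted p = 0.0196; 0 of 15, and 3 adjusted over the list alone; adjusted p = 0.527 with an estimated correlation). The medians with slide as a block were 0.61, 0.31, 0.44 and 0.23 in that order, with 1, 2, 2 and 3 genes rising. The camera adjusted p were 5.38e-04, 0.00149, 1.76e-04 and 0.0560, and from 0.471 to 0.804 with an estimated correlation in that fit. Within slides 1 and 2 the medians were 0.81 and 0.28, 0.35 and 0.37, 0.39 and 0.54, and 0.14 and 0.27. Htr2a was 0.93 ± 0.19 against naive (adjusted p = 0.0655), Per3 0.94 ± 0.19 (0.0655), S100a9 2.49 ± 0.77 (0.114), Nr3c1 -0.46 ± 0.13 (0.102) and Tlr4 -0.71 ± 0.35 (0.273). S100a8, above background in 3 of 3 resilient and 0 of 5 naive mice, had a bound of 2.24-fold and did not pass (adjusted p = 0.0818). Htr2a, Per3 and Hspa5 passed with slide as a block (adjusted p = 0.0369, 0.0293 and 0.0411), but each lost that call when some mouse was left out (highest 0.242, 0.201 and 0.263).

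Other members of the lists without a call in resilient mice had these values against naive, with limma adjusted p from 0.0655 to 0.220: Bhlhe40 0.80 ± 0.16, Arc 0.87 ± 0.24, Fosb 0.43 ± 0.12, Hspa1a 0.87 ± 0.26, Chordc1 0.47 ± 0.14, Creld2 0.53 ± 0.16, Grin2b 0.75 ± 0.25, Gria3 0.38 ± 0.13, Syp 0.43 ± 0.15 and Syn1 0.40 ± 0.15. In the same range were Nr3c2 0.42 ± 0.17, Insig1 0.53 ± 0.15, Txnrd1 0.35 ± 0.10, Prdx1 -0.49 ± 0.14, Stat2 0.26 ± 0.10, Psmb8 -0.61 ± 0.20, Maoa -0.31 ± 0.13, Ndufb8 -0.52 ± 0.15 and Cox6c -0.65 ± 0.20. Of these Bhlhe40 (adjusted p = 0.0369), Arc (0.0293), Hspa1a (0.0483), Creld2 (0.0408), Txnrd1 (0.0369) and Cox6c (0.0386) passed with slide as a block. All 6 lost that call when some mouse was left out (highest adjusted p from 0.201 to 0.301).

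Meningeal (-1.16; camera adjusted p = 0.0171), endothelial (-0.49; 0.0429) and astrocyte (-0.34; 0.0179) medians were lower in resilient than naive mice, and neuron (0.28; 0.0171) and inhibitory neuron (0.26; 0.0345) medians higher, with 0 genes past the threshold. None of these 5 passed with an estimated correlation (adjusted p from 0.569 to 0.663) or with slide as a block (camera adjusted p from 0.159 to 0.254). Meningeal and endothelial medians were -1.76 and -0.72 within slide 1 and 0.65 and 0.29 within slide 2, which held 1 resilient mouse.

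In the fit with slide as a block 511 genes passed for resilient against naive mice, 295 higher and 216 lower, including all 22. The 22 kept their direction within slides 1 and 2. Each slide has 1 mouse in 1 of the groups and is part of the pooled data that chose the genes. Leaving out 1 mouse gave 0 genes for naive 2, naive 3, susceptible 1, susceptible 3, susceptible 5 and resilient 3, 1 for naive 4 and resilient 1, 2 for resilient 2, 6 for susceptible 2 and 76 for susceptible 6. All 18 named calls were lost in at least 1 of these fits (highest adjusted p 0.302), and 0 of 18 held in every such fit with slide as a block. In those fits the 511 genes became 0 without naive 1, naive 2 or resilient 3, 1 without resilient 1, 2 without susceptible 5, 4 without susceptible 2, and 99 without resilient 2. They became 199 without naive 4, 327 without naive 3 and 1187 without susceptible 6.

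Susceptible and resilient mice were compared to ask whether transcripts differed between defeated mice that were classed differently by behaviour. None of 14453 genes passed in limma (smallest adjusted p 1.000), and 108 genes had an unadjusted p under 0.05, where 722.65 would by chance. The fit with slide as a block passed 0, and 279 had such a p. Of the 376 genes that differed between susceptible and naive mice, 12 had an unadjusted p under 0.05 between the defeated groups in limma. A uniform p would give 18.8, but over all genes the count was also far under chance, at 108 against 722.65. The 376 were chosen partly on susceptible values, so the 12 do not show whether these genes differ between the defeated groups. The genes with the smallest p were, higher in susceptible mice, Pilra (0.58 ± 0.14), an inhibitory immune receptor, Tjap1 (0.42 ± 0.13), Fancb (0.37 ± 0.12) and Ms4a6d (0.77 ± 0.28), and, lower, Erich1 (-1.42 ± 0.34), Adamts3 (-0.89 ± 0.24), Nexn (-0.65 ± 0.19), Ankrd52 (-0.50 ± 0.15) and Aoah (-0.53 ± 0.17). Adamts3 was above background in 2 of 6 susceptible mice, and Nexn and Aoah in 4 of 6. S100a8 was 1.15 ± 0.66 higher and Lcn2 0.52 ± 0.49 higher in susceptible mice, each with an adjusted p of 1.000, and Tlr4 was -0.21 ± 0.34. Leaving out 1 mouse moved Lcn2 between -0.19 and 1.05 and S100a8 between 0.70 and 1.56, and within slide 2 Lcn2 was -0.78. On simulated data of 14453 genes, 13.7%, 73.1% and 96.7% of changes of 0.5, 1 and 2 on the log2 scale were recovered for this comparison. The simulated noise was independent between genes, while real genes were correlated, so these shares may not hold for the real arrays.

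By camera, 7 of 29 lists differed between susceptible and resilient mice, with 0 genes past the threshold in any, and 0 did so with an estimated correlation. Immediate early genes (median -0.10; camera adjusted p = 0.0171) and circadian genes (-0.12; 0.0445) were lower in susceptible mice, as were oligodendrocyte markers (-0.42; 0.0171). Oxidative phosphorylation genes (0.09; 0.0141), blood leukocyte markers (0.19; 0.0134), erythroid genes (0.70; 0.0179) and microglia markers (0.09; 0.0474) were higher. With slide as a block camera adjusted p was 2.78e-04 for immediate early genes, 1.34e-04 for blood leukocyte markers and 0.0210 for oxidative phosphorylation genes. It was from 0.121 to 0.566 for the other 4. Striatal, oligodendrocyte precursor and pericyte lists passed only in that fit (0.0226, 0.0114 and 0.0320). None of these block calls held with an estimated correlation (camera adjusted p from 0.471 to 0.804). Within slides 1 and 2 the immediate early median was -0.15 and -0.19, while the oligodendrocyte median was -0.47 and 0.31 and the erythroid median 1.66 and -0.58. The members with an unadjusted p under 0.05 in limma among those named here were the activity-induced genes Fosb (-0.27 ± 0.11) and Gadd45b (-0.35 ± 0.16), each with an adjusted p of 1.000. Values with an unadjusted p of 0.05 or more were Msmo1 0.68 ± 0.38, Stard4 -0.20 ± 0.14, Drd5 0.48 ± 0.36, Tac1 0.43 ± 0.25, Npy 0.23 ± 0.20, Chordc1 0.20 ± 0.14, Hspe1 0.13 ± 0.11, Shank2 0.20 ± 0.11, Grin2b -0.41 ± 0.24, Ndufb8 0.20 ± 0.14, Cycs 0.15 ± 0.13, Gpx1 0.16 ± 0.14 and Txnrd1 -0.11 ± 0.10. Leaving out 1 mouse moved Msmo1 between -0.08 and 1.07, Drd5 between -0.01 and 0.95 and Tac1 between 0.08 and 0.80. Likewise Pdia4 was 0.16 ± 0.15, Xbp1 0.12 ± 0.13, Irf9 0.12 ± 0.20, Gbp2 -0.50 ± 0.45, Per1 -0.14 ± 0.13, Dbp -0.19 ± 0.14, Ciart -0.33 ± 0.19, Syn2 -0.16 ± 0.12, Syt1 -0.23 ± 0.15 and Hmgb1 -0.45 ± 0.25.

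The responses of both defeated groups were set side by side over all genes. The log2 differences against naive correlated at r = 0.88 over 14453 genes, which are not independent replicates, and both differences use the same naive mice. Unchanged groups simulated against those mice gave r = 0.45, and the covariance was 0.0918 against a simulated 0.0180. When the naive mice were split so that each comparison had its own, the median r over 20 splits was 0.59 (from 0.0901 to 0.727) and the covariance 0.0714. All 376 genes that differed in susceptible mice had the same sign in resilient mice, with a median size ratio of 0.98, but part of this comes from the shared naive mice. For the 376 leading genes of simulated unchanged groups these values were 90.3% and 0.549, and with the naive mice split their medians were 95.6% (from 69.9% to 98.7%) and 0.685 (from 0.177 to 0.963). There were 20 genes past the threshold in both comparisons, 11 rising and 9 falling in both, and no value for unchanged groups was computed for this count. With the naive mice split the median overlap was 0 (from 0 to 1), but in 17 of 20 splits at least 1 comparison had 0 calls. Both defeated groups also lay in slide row 2 and were brighter than naive mice on slides 1 and 2 (resilient mean 8.06 and 7.97, naive 7.31 and 7.30). Neither the simulation nor the splits remove row or brightness, so these cannot be told apart from a shared response to defeat.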

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

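The tests of brightness, meningeal tissue, blood, neutrophils, inflammation, ribosomal protein genes and signal-matched lists were chosen after the result was seen, and the criterion for blood was rewritten after its own result was seen; the splits of the mice were not.

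The first pattern is the set of 376 genes that differed between susceptible and naive mice. Of 100 of the 462 splits of the 11 mice, 6, the real one included, gave as many genes, so chance was not excluded; the highest other split gave 955 and set the 4 mice of slide 3 with susceptible 2 and susceptible 4, so it followed the scan day. When slide was a block, 100 of the 108 splits that keep each slide's makeup were run, and 1, the real one, reached 2213 genes. The highest other gave 74, which argues against chance there. The real split also follows slide row, so it does not tell defeat from row. With brightness in the fit 376 of 376 genes were kept. Over all arrays, however, brightness mostly separated the scan days, at 8.54 or above on slide 3 and 8.17 or below on slides 1 and 2. That fit therefore cannot exclude brightness. Meningeal tissue as the whole source is argued against by the 267 genes kept with slide and the meningeal markers in the fit. Without slide, the fit with those markers kept 4 genes, with 0.913 of the median difference left and standard errors 1.15 times as large. Brightness within slides cannot be told apart from defeat: with slide and brightness 0 genes passed, a median 0.779 of the difference was left and standard errors were 1.51 times as large, and a response to defeat, the slide row and brightness may each contribute.

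The second pattern is the rise of S100a8, S100a9 and Lcn2 in susceptible mice. Whether blood left in vessels is a source was not settled, since under the criterion first set the lost calls counted in favour of blood. With slide and the globin mean in the fit the lowest share left was 0.849. S100a8, above background in no naive mouse, cannot carry this test. S100a9 went from 3.42 ± 0.63 to 2.90 ± 0.82 and Lcn2 from 3.33 ± 0.44 to 3.58 ± 0.58, so most of their difference did not follow globin transcripts. In that fit, with its larger standard errors, 0 of all genes passed in limma, with adjusted p of 0.178 for S100a9 and 0.161 for Lcn2. Neutrophils in the tissue may remain a source: 29 other neutrophil transcripts, 13 of them above background on no array, had a median of -0.0450 (camera p = 0.626; p = 0.849 with an estimated correlation), but Camp was 0.36 ± 0.11 higher at an unadjusted p under 0.05 in limma, and Retnlg, Clec4d and Ltf, each above background in 0 of 5 naive mice, were above it in 4, 3 and 1 of 6 susceptible mice. A wider response to inflammation in the circulation is not shown for Lcn2 and Lrg1: 20 other genes of such a response had a median of 0.195 with slide as a block (camera p = 0.0368; p = 0.315 with an estimated correlation), but the values of 5 were seen before the list was written, and the other 15 had a median of 0.0861 (camera p = 0.514; p = 0.671 with an estimated correlation).

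The third pattern is a joint shift of ribosomal protein genes, whose median in susceptible mice was -0.401 with 82 of 84 lower (camera p = 4.01e-26; p = 0.0972 with an estimated correlation). Singly, 2 passed, and 55 did so in the fit with slide as a block; the median within slides was -0.31, -0.69 and -0.18. Brightness acting on all bright spots alike is argued against, since the lowest median among 10000 lists of other genes matched on signal was -0.262. Brightness within slides cannot be told apart, as 0.470 of the shift was left with slide and brightness in the fit, and quantile normalisation left a median of -0.14. A response to defeat, the slide row and an effect of brightness on these transcripts may therefore each account for part of it.

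For resilient against naive mice, 2 of the 56 splits of the 8 mice reached the real 22 genes, under the share set for chance. However, the other split was naive 1, 2 and 3, the naive mice of scan day 1, against the rest, with 1420 genes. Those were the dimmest of the 8 arrays, at 7.25 to 7.36 against 7.96 to 8.64 for the rest, so that split separated the arrays by brightness. Keeping slide as a block, only 9 splits exist, too few for a share under 0.05; the real split gave 511 genes and the highest other 0, and 1 split, the real one, was as high. For susceptible against resilient mice the real count was 0, which all 84 splits must reach (highest 24), so the splits say nothing about chance there.

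Single mice lay far from the rest of their group in 6 of 148 sets of values, where chance gives 7.4. Naive 3 had the highest naive Fkbp5 signal, at 2.36 against 1.72 for the next. Susceptible 6 had the lowest Tmem52 signal, at -3.02 against -2.08, and the highest Ston2 signal, at -1.35 against -1.75. Susceptible 2 had the lowest Rsrp1 signal, at 2.61 against 3.11. Susceptible 4 had the lowest mean of Toll-like receptor and cytokine genes relative to naive, at 0.14 against 0.45, and susceptible 6 the lowest mean of striatal markers, at 0.0254 against 0.117.

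Lists that differed between susceptible and resilient mice by camera are repeated with their medians: immediate early genes at -0.10, circadian genes at -0.12, oxidative phosphorylation genes at 0.0937, microglia at 0.0905, oligodendrocytes at -0.42, blood leukocytes at 0.19 and erythroid genes at 0.70. None held with an estimated correlation (camera adjusted p from 0.527 to 0.663). Circadian, microglia, oligodendrocyte and erythroid lists did not pass with slide as a block (camera adjusted p from 0.121 to 0.566). Probes without a gene name lay outside the comparisons. Of 10982 of them 0 passed without a block in limma in any comparison (1978 and 1671 at an unadjusted p under 0.05 for susceptible and resilient against naive). In fits with slide as a block 1317 passed for susceptible against naive mice, 1053 of them lower, and 777 for resilient against naive mice, 681 of them lower. Among genes with a name most calls of such fits went the other way, with 1276 of 2213 and 295 of 511 higher. The cause of this difference, brightness included, was not tested.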

How the results depend on the processing

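The alternatives with brightness, meningeal markers or scan day 1 alone were chosen after the result was seen. For each changed count the cause was not tested unless stated.

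The genes changed in susceptible vs naive mice numbered 376. Quantile normalisation gave 614 genes (349 shared), normexp 136 (113 shared) and all probes without a filter 35 (33 shared). Counts were 2213 with slide as a block, 1759 with slide as a random block and 2501 with scan day as a block. Brightness as a covariate gave 1464 genes, slide and brightness 0 (1216 at an unadjusted p under 0.05 in limma), meningeal markers 4, and slide and meningeal markers 729. Scan day 1 alone gave 1940, the 2 groups alone 66, an adjusted p under 0.10 gave 1423, and an unadjusted p under 0.05 with at least 1.5-fold gave 663. Slides 1, 2 and 3 alone gave 20, 2022 and 0 (968 at an unadjusted p under 0.05 in slide 3). Leaving out 1 mouse gave 27 to 869, and 719 to 2801 with slide as a block.

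The genes changed in resilient vs naive mice numbered 22, and 38 with quantile normalisation. Normexp (2256 at an unadjusted p under 0.05 in limma), no filter, the filter on 3 arrays, the 2 groups alone, and slide with brightness each gave 0. With slide and brightness 531 genes had an unadjusted p under 0.05 in limma, where 722.65 would by chance. For the 22 genes a median 0.698 of the difference was left there, with standard errors 1.72 times as large. Brightness within slides cannot be told apart from defeat in resilient mice either. Counts were 511 with slide as a block, 150 with slide as a random block and 1467 with scan day as a block. Array weights, which stopped before convergence, gave 758, eBayes with trend and robust settings 63, brightness 1098, meningeal markers 2, and slide and meningeal markers 253. Scan day 1 alone gave 1630, an adjusted p under 0.10 gave 324, the unadjusted p with 1.5-fold 788, and slide 2 alone, with 1 resilient mouse, 86. Leaving out 1 mouse gave 0 to 76, and 0 to 1187 with slide as a block. The genes changed in susceptible vs resilient mice numbered 0, 26 with the unadjusted p and 1.5-fold, 1 within slide 2, and 0 to 1 when 1 mouse was left out.

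A replicate block, which pairs mice of the same number, gave 1711 genes (810 higher, 901 lower, against 237 and 139 without it) and 727 genes for the comparisons with naive mice. Susceptible 6, the only mouse with its number, adds nothing to the differences in that fit. Leaving it out without a block gave 869 and 76 genes, so the rise cannot be credited to pairing alone. Whether the numbers pair mice was left open: deviations of same-number mice correlated at r from -0.38 to 0.71, 8 of 11 pairs over 0.1, and a naive mouse correlated best with its own number in 1 of 5 cases among susceptible and 2 of 3 among resilient mice.

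Of 87 tests of lists, 28 passed by camera and 0 with an estimated correlation. With slide as a block 17 passed (14 of the 28), and 0 with slide as a block and an estimated correlation. By fry 6 passed (5 of the 28, and circadian genes in susceptible against naive mice), and 19 to 32 passed by camera when 1 mouse was left out. Medians with a reversed sign were, within slide 3, neuron markers in susceptible against naive mice (-0.0122), and, within slide 2, endothelial (0.289) and meningeal (0.646) markers in resilient against naive mice. Between susceptible and resilient mice, microglia (-0.104), oligodendrocyte (0.307) and erythroid (-0.578) medians reversed within slide 2, and the microglia median was -0.000264 with slide as a block and 0.0082 with a replicate block, where its test reversed. Of 47 named calls, 20 passed with normexp and 6 to 47 when 1 mouse was left out.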

Other observations

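The list of the response of brain tissue to systemic inflammation was written after the first results, when the values of Il1r1, Cd14, Ptgs2, Socs3 and Osmr had been seen, so those 5 genes do not test it. In susceptible against naive mice Socs3, a feedback inhibitor of cytokine signalling, rose by 0.79 (limma adjusted p = 0.0312) and Tnfrsf1a, a tumour necrosis factor receptor, fell by 0.41 (adjusted p = 0.0431). When slide was a block, 5 of 20 genes rose and 2 fell: Cd14, a co-receptor for bacterial lipopolysaccharide (0.60 ± 0.10), Socs3 (0.76 ± 0.15), the astrocyte serpin Serpina3n (1.21 ± 0.27), the oncostatin receptor Osmr (0.89 ± 0.24) and the interleukin 1 receptor Il1r1 (1.22 ± 0.35) rose, and Tnfrsf1a (-0.40 ± 0.09) and Upp1 (-0.36 ± 0.10) fell. The endothelial adhesion genes Vcam1 (-0.08 ± 0.25) and Selp (-0.12 ± 0.13) did not pass. Among the 15 members not seen before, 1 rose and 2 fell with slide as a block, and 8 were higher.

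Ribosomal protein genes had a median of -0.50 in resilient against naive mice, with 80 of 84 lower and 0 past the threshold singly (29 lower with slide as a block). The median was -0.21 with quantile normalisation, 0.425 of the size, and -0.23 with slide and brightness in the fit, 0.471 of it. In susceptible against resilient mice it was 0.09. On single arrays their mean relative to naive ranged from -0.30 in naive 5, the brightest naive array, to 0.48 in naive 3, the dimmest array. It ranged from -0.58 to -0.25 in the 9 defeated mice. On slide 3 it was -0.32 in susceptible 6, about as bright (8.63) as naive 5 (8.64). There it was -0.24 in naive 4 (8.54) and -0.54 in susceptible 5 (9.24).

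Genes called between susceptible and naive mice on scan day 1 were followed on scan day 2. Of 1940 genes, 1701 (87.7%) differed in the same direction on day 2, with a median of 0.61 on day 1 and 0.20 on day 2, 0.29 in susceptible 5 and 0.12 in susceptible 6. The genes are not independent, and no share for unchanged groups was computed. Brightness was 9.24 in susceptible 5 and 8.63 in susceptible 6, against 8.54 and 8.64 in the naive mice of day 2. Slide row also differed between the groups on both days, so the shared direction does not tell defeat from row or brightness.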
